A study of Mus musculus with 12 samples.

How the data were processed

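Bulk RNA was measured in the colon of 2-week-old mice that lacked Il10 or that lacked both Il10 and Tnfr1 (the gene Tnfrsf1a, which encodes TNF receptor 1). Per the labels' protocols, dissected colons were homogenized in Trizol, total RNA was column-purified, and stranded mRNA libraries were read as single-end reads. The submitters' processing notes name CASAVA, kallisto and sleuth, without versions, and the build mm10. How these tools were set is not given in the sources used here.

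The deposited values are listed by transcript, with an abundance for each library and the authors' own comparison of the genotypes. Per the file headers it also pairs each transcript with a gene identifier and symbol. The per-library abundances are a never-negative signal that the authors scaled before depositing: they are not counts, and each library sums to between 804109 and 1378971. Against the authors' mean log count, the abundance of a transcript carried a slope of 1.005 on the log of transcript length over 13060 transcripts, so the values were divided by length. The sums differ between libraries, as a scaling between libraries would leave them, although the headers do not name one. The deposited p-value, q-value, fold ratio, log2 fold and mean on a natural log scale are the authors' own, per the file headers, and each is quoted only as such. The authors' fold lay within 1% of the ratio of the means of the libraries used here for only 6.89% of transcripts. Which libraries or which computation gave the authors' values is therefore not known. They were never set against a mean or SD from this work as if from the same samples. Since the values are not counts, the sequencing depth of each library is unknown and no counting interval is given.

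Of the 12 samples in the labels, 11 have a column whose name starts with the sample's title. The remaining 1 column of per-sample values matched no title, and 1 Il10-/- sample (replicate 4) matched no column. Neither was used in any step. The comparison was therefore 5 Il10-/- mice (replicates 1, 2, 3, 5 and 6) against 6 Il10-/- Tnfr1-/- mice. Replicates are numbered in the order of the samples and are not paired across genotypes. The labels do not state litter, sex or batch. Each sample's title is a number whose first digit, 1 to 4, has a meaning the labels do not give: names that start with 1 cover 3 Il10-/- and 2 Il10-/- Tnfr1-/- mice, names that start with 2 or 3 are all Il10-/- Tnfr1-/-, and names that start with 4 are all Il10-/-. The digit can therefore be separated from genotype only among names that start with 1, where 3 animals against 2 cannot give an exact p below 0.1.

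For transcripts listed more than once, the first row was kept and the 866 repeated rows were dropped. The remaining 113193 transcripts were summed to 35688 genes by the table's gene identifier. Of the transcript identifiers, 109294 (96.6%) matched GENCODE release M21, which supplied coordinates on the mouse build mm10, transcript classes and transcript sequences. The test planned before the data were examined assumed estimated counts, and the fallback planned for other units was used: limma (version 3.58.1 in R 4.3.3, with version 1.17.8 of data.table), with an intensity trend and robust variance moderation, on log2(value + 0.5), for genes with a value over 1 in at least 6 samples. This left 13293 genes and, with the same rule, 26074 transcripts. With 5 Il10-/- samples, the filter is not even between the genotypes. A gene over 1 in the Il10-/- samples alone was left out, while a gene over 1 in the 6 Il10-/- Tnfr1-/- samples alone was kept. P-values are two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(value + 0.5) scale, in the direction Il10-/- Tnfr1-/- minus Il10-/-, and understate the change of low genes. Values given as mean ± SD are on the deposited scale.

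The 39 gene lists, the grouping of samples, the tests and the rule for named genes were fixed before the data were examined. Lists were tested with limma's camera, which compares a list with the other genes, at a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry. A list score is the mean over a list's tested members of the log2 value centred on the gene's mean over the 11 samples. Scores were compared between genotypes by an exact two-sided permutation test over all 462 assignments, whose smallest p is 0.00216, with adjustment over the 39 lists. The spread of each score was compared by an exact permutation test of the variance ratio. Named genes are Tnfrsf1a and Il10; the 10 genes of smallest p with a mean value of at least 1, since fewer than 10 genes passed the threshold, leaving out predicted genes, receptor segments and sex-linked genes; 4 members of smallest p of each of the 6 lists of smallest camera p; and 2 members of smallest p of each other list described. Which lists are described beyond those 6 was chosen after their results were seen: the other 7 that passed camera, and B cell, macrophage and monocyte, interferon gamma response, mature colonocyte, goblet cell and the TNF lists. The B cell list was left out at one stage because the sign of a member changed between settings, and was put back. Any other gene named was chosen after its values were seen.

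The gene test was tested on simulated data for this comparison, with 13293 genes. When 100 genes were changed by a log2 fold change of 2 and 100 by 1, on the real residual profiles of whole animals, it recovered 85% of the former and 37% of the latter, with 1 unchanged gene called. With independent noise it recovered 84% and 40%, with 5 unchanged genes called. All of these genes were changed together in a single draw. Adjustment is stricter when fewer genes change, so these shares do not give the power to call a few changed genes.

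Alternatives chosen before the data were examined were no filter on low values, pseudocounts of 0.1 and 1, the first digit of the name as a covariate, only names that start with 1, a fold change minimum, leaving out sex-linked genes and receptor segments, other list tests, other windows around Tnfrsf1a, and leaving out each sample in turn. Alternatives chosen after seeing the data were limma without robust moderation, rescaling each sample to an equal total, median-ratio size factors, quantile normalization, and the smooth muscle list score, the share of value in retained-intron transcripts or whether Ptges3-ps was above 0 as a covariate. The neutrophil list was also tested without Ly6g after seeing the data. Correlations of library measures and the smooth muscle score with principal components were also computed after seeing the data. Tests and normalizations that need counts were not run. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.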

Results

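The data were abundances of transcripts in the colon of 2-week-old mice, all of which lacked Il10, the gene of the anti-inflammatory cytokine interleukin 10. The comparison was between 5 Il10-/- mice and 6 Il10-/- Tnfr1-/- mice, which also lacked TNF receptor 1, encoded by Tnfrsf1a. Loss of Il10 is a widely used setting for spontaneous colitis in mice, and the design asks how the colon of such animals differs when TNF receptor 1 is missing. There was no wild-type colon in the series, so each value is relative to the other genotype. The abundances of a library summed to between 804109 and 1378971, and between 41.7% and 55.1% of transcripts were at 0 in a library. Depth is unknown because the values are not counts.

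The targeted genes were examined first. Tnfrsf1a, on chromosome 6 from 125349362 to 125362484 on the plus strand of mm10, had a summed abundance of 47.9 ± 18.5 (SD, n = 5) in Il10-/- and 14.8 ± 2.35 (SD, n = 6) in Il10-/- Tnfr1-/- colons, or 30.9% of the Il10-/- mean. All 6 Il10-/- Tnfr1-/- samples, between 12.0 and 17.0, lay below all 5 Il10-/- samples, between 30.6 and 78.1. The log2 fold change was -1.60 ± 0.22 (SE), with an exact permutation p of 0.00216, the smallest these samples can give. Nearly all of this signal was on 1 transcript, ENSMUST00000032491.14, at 46.8 ± 18.5 and 13.7 ± 2.58. The remaining signal in the Il10-/- Tnfr1-/- samples cannot be placed along the gene with values per transcript, so reads outside the deleted part cannot be told from reads of an intact gene. In the authors' deposited table this transcript had the smallest q-value of the 43192 tested, 0.0811.

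Il10 itself, on chromosome 1 from 131019845 to 131024974, was targeted in both genotypes and still carried signal in every sample. It was lower in the mice that also lacked TNF receptor 1: 5.14 ± 1.57 (SD, n = 6) against 15.3 ± 6.44 (SD, n = 5), again with no overlap between the genotypes. The log2 fold change was -1.44 ± 0.28 (SE), with an exact permutation p of 0.00216 over the 462 assignments (0.00216 after adjustment over the 2 targeted genes). Since the part of the gene that was removed is not given in the sources used here, this signal checks nothing about the Il10 label. Among names that start with 1, where an exact p cannot go below 0.1, the log2 fold changes were -1.83 for Tnfrsf1a and -1.37 for Il10, each with an exact p of 0.1.

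**Figure D1:**
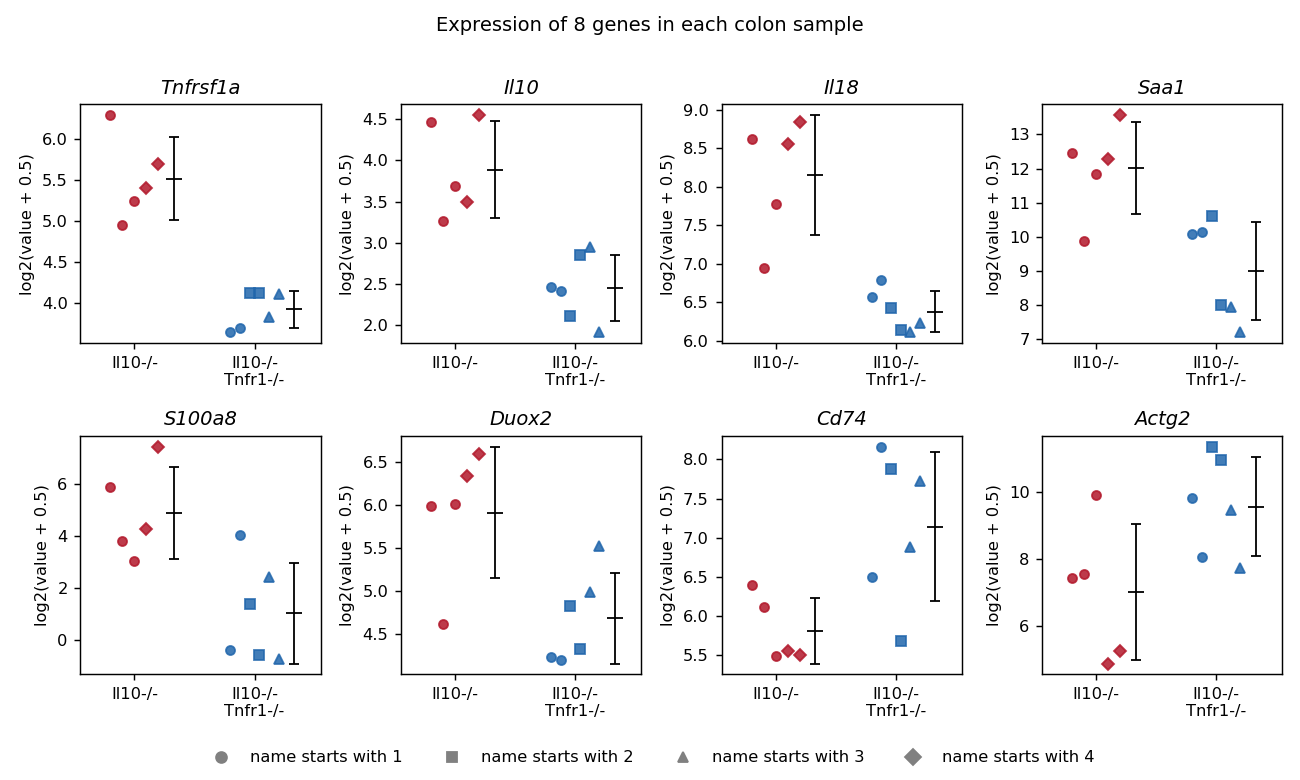
Abundance of 8 genes on a log2(value + 0.5) axis in each colon sample, with Il10-/- in red (n = 5) and Il10-/- Tnfr1-/- in blue (n = 6); the marker shape gives the first digit of the sample's name, and the bars show the mean and SD of the log2 values. For Tnfrsf1a, Il10 and Il18 every blue point lies below every red point, while Saa1, S100a8, Duox2, Cd74 and Actg2 overlap.

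Over all genes, 8 of the 10 named genes of smallest p were lower on average in Il10-/- Tnfr1-/- colons, Tnfrsf1a and Il10 among them. Il18, an inflammasome-processed cytokine of the epithelium, was at 313.9 ± 138 in Il10-/- and 84.1 ± 16.2 in Il10-/- Tnfr1-/- samples, a log2 fold change of -1.77 ± 0.31 (SE), lower in 6 of 6 samples than any Il10-/- sample. Among names that start with 1 its log2 fold change was -1.10 (exact p = 0.2). The serum amyloid gene Saa2 was at 12.0 ± 10.4 and 1.33 ± 0.756, and the phospholipase gene Pla2g4f at 17.6 ± 10.02 and 4.60 ± 1.67. Both also separated the genotypes without overlap. Sh3tc1 (log2 fold change -0.70), Fer1l4 (-1.67) and Rabggta (-0.63) were lower too, while the serine protease gene Prss23 (1.68) and the transport adaptor gene Trak2 (0.72) were higher. None of these passed the threshold over all genes. Limma with Benjamini-Hochberg adjustment called 0 of 13293 genes, with the smallest adjusted p, 0.123, for Tnfrsf1a and 0.535 for Il18, Il10 and the others just named. At an unadjusted p under 0.05 there were 1117 genes, 639 higher and 478 lower, against 665 expected by chance. Without the filter on low values, 54.1% of 1598 such genes were higher, against 57.2% with it. Scaling moved this balance: with an equal total per sample, an alternative chosen after seeing the data, the median log2 fold change of all genes went from 0.05 to 0.18 and 75.5% of 907 such genes were higher. With median-ratio size factors, 40.2% of 1193 were higher. Without Il10-/- replicate 6 there were 474 such genes and without Il10-/- replicate 1 there were 2445. Without Il10-/- replicate 2, limma called 2 genes, Tnfrsf1a (adjusted p = 0.0333) and Il18 (adjusted p = 0.0242), both lower; with quantile normalization it called Tnfrsf1a alone (adjusted p = 0.0338). The smallest adjusted p over all alternatives lay between 0.0242 and 1.

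At the level of single transcripts the outcome was the same: 0 of 26074 passed limma's adjusted threshold, with a smallest adjusted p of 0.574 and 1645 at an unadjusted p under 0.05 against 1304 expected. Without Il10-/- replicate 2, 1 transcript passed. The authors' deposited table, whose folds mostly differ from ratios of the libraries used here, has 0 transcripts with a q-value under 0.05. It has 1 under 0.10 and 2948 with a p-value under 0.05. In that table the leading transcripts of Il18, Il10, Pla2g4f and Saa1 have log2 folds of -1.70, -1.52, -2.22 and -2.88, each with a q-value of 0.684. In the present data 78 genes (0.587%) separated the genotypes without overlap, 42 higher and 36 lower, where chance gives 57.5 (0.433%).

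The gene lists were tested next, and what follows describes 13 lists that passed camera at the preset correlation. With an estimated correlation 0 of them passed. Other splits of the same samples gave a median of 9 lists past camera at the preset correlation. A small camera p at that correlation, in any setting below, is therefore not by itself evidence for an effect of genotype. Epithelial antimicrobial defence genes, which the gut lining switches on in contact with microbes, were lower in Il10-/- Tnfr1-/- colons: 21 of the 23 tested members had a lower mean, and camera gave the smallest p of the 39 lists (adjusted p = 2.81e-08, and adjusted p = 0.461 with an estimated correlation). The acute-phase gene Saa1, one of the most abundant members, was at 5450 ± 4107 in Il10-/- and 738.3 ± 599 in Il10-/- Tnfr1-/- samples, a log2 fold change of -3.00 ± 0.74 (SE), but -1.29 among names that start with 1 (exact p = 0.4). The epithelial oxidase gene Duox2 was at 65.5 ± 26.9 and 26.6 ± 10.7 (-1.23). The small proline-rich gene Sprr2h was at 13.6 ± 12.5 and 2.08 ± 3.50 (-2.62). Saa1 and Saa2 are close copies, so how their reads were divided is uncertain. Adjusted over the list alone, 6 members were called, all lower; over all genes, 0 were. The list score differed by -1.18, with an exact permutation p of 0.00433, which became 0.0844 after adjustment over the 39 lists. It differed by -0.66 among names that start with 1 (exact p = 0.2) and, with the smooth muscle score as a covariate, by -0.66 ± 0.28 (SE) in place of -1.18 ± 0.34 (SE). The camera call held in every alternative run at the preset correlation, with adjusted p between 2.8e-14 and 0.0164.

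Neutrophil genes were also lower, with a lower mean in 4 of the 5 tested members (camera adjusted p = 0.00322, adjusted p = 0.491 with an estimated correlation). Only these 5 of the 20 listed passed the filter, which a gene over 1 in the Il10-/- samples alone could not pass. S100a8, a subunit of the neutrophil protein calprotectin, was at 53.7 ± 68.1 in Il10-/- and 3.88 ± 6.08 in Il10-/- Tnfr1-/- samples (log2 fold change -3.85 ± 0.97, SE), while S100a9 was at 19.3 ± 21.9 and 3.10 ± 4.46. Ly6g was at 167.2 ± 163 and 23.4 ± 27.1, above S100a8 in 9 of 11 samples, and Ltf was at 11.6 ± 13.5 and 2.34 ± 0.751 (log2 fold change -1.19, and -0.59 without Il10-/- replicate 6). Without Ly6g, whose source is open, the other 4 members still passed camera (adjusted p = 0.0225), with a score difference of -1.78 (exact permutation p = 0.0216), a test added after seeing the data. Without the filter on low values the list mean was -0.64. Adjusted over the list alone, 3 members were called, all lower. The score differed by -2.03 (exact permutation p = 0.0216, adjusted 0.274) and by -1.41 among names that start with 1 (exact p = 0.5). Without Il10-/- replicate 1 the camera call was lost (adjusted p = 0.101), while the list mean was -1.69 and S100a8, S100a9 and Ly6g had log2 fold changes of -3.60, -2.22 and -2.46. With the first digit of the name as a covariate the call was also lost (adjusted p = 0.0642), with a score difference of -1.41 ± 1.23 (SE) in place of -2.03 ± 0.70 (SE), while the same estimate among names that start with 1 passed (adjusted p = 0.0494). With the smooth muscle score as a covariate it was lost at -1.42 ± 0.81 (SE, adjusted p = 0.0671).

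The 4 inflammatory cytokines that could be tested of the 24 listed were all lower on average (camera adjusted p = 0.0224, adjusted p = 0.491 with an estimated correlation). They included Il18 and Tnf, the ligand of the missing receptor, which was at 5.37 ± 4.16 in Il10-/- and 1.98 ± 0.66 in Il10-/- Tnfr1-/- samples (log2 fold change -0.96 ± 0.45, SE). The other members, Lif and Il1rn, were nearly unchanged, with log2 fold changes of -0.137 ± 0.267 (SE) and -0.005 ± 0.551 (SE). The lower list therefore rests on Il18 and Tnf. Adjusted over the list alone, 1 member, Il18, was called. The score differed by -0.72 (exact permutation p = 0.0368, adjusted 0.287), and the camera call was lost in 3 settings. The list mean was then -0.53 without Il10-/- replicate 1, -0.18 without the filter on low values, and -0.59 ± 0.36 (SE) in place of -0.72 ± 0.29 (SE) with the smooth muscle score as a covariate. Tnf had a log2 fold change of -0.63 without Il10-/- replicate 6. The squamous epithelium list, reduced to Krt14 and Krt10, was lower as well (camera adjusted p = 0.032, adjusted p = 0.491 with an estimated correlation; score difference -0.59, exact permutation p = 0.00216, adjusted 0.0844). Krt14 was at 3.48 ± 1.91 and 1.56 ± 0.601, and Krt10 at 7.09 ± 1.84 and 5.62 ± 0.607; adjusted over the list alone, Krt14 was called. The camera call was lost without Il10-/- replicate 1, 2 or 3 (list means -0.51, -0.66 and -0.53) and without Il10-/- Tnfr1-/- replicate 6 (-0.51). It was also lost among names that start with 1 (-0.65, adjusted p = 0.0678), where the list mean was not smaller, and the same estimate passed with the first digit as a covariate (adjusted p = 0.0463). Without the filter on low values the mean was -0.21. Krt10 had a log2 fold change of -0.28, and -0.16 without Il10-/- replicate 3.

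In the other direction, MHC class II genes, which present antigen to helper T cells, were higher in Il10-/- Tnfr1-/- colons in all 7 tested members (camera adjusted p = 4.43e-05, adjusted p = 0.491 with an estimated correlation). Cd74, the class II invariant chain, was at 57.7 ± 17.9 in Il10-/- and 165 ± 91.9 in Il10-/- Tnfr1-/- samples (log2 fold change 1.33 ± 0.41, SE). H2-Eb1 was at 20.8 ± 4.74 and 56.0 ± 28.7, H2-Aa at 37.2 ± 11.2 and 98.3 ± 52.6, and H2-DMa at 4.69 ± 1.54 and 11.03 ± 5.60. Adjusted over the list alone, 6 members were called, all higher. The score differed by 1.08 (exact permutation p = 0.0281, adjusted 0.274) and by 0.96 among names that start with 1 (exact p = 0.1, the smallest possible there). That difference leans on Il10-/- Tnfr1-/- replicate 2, at 1.258. Replicate 1, at -0.144, lay barely above Il10-/- replicate 1, at -0.169. With the first digit of the name as a covariate the difference was 0.96 ± 0.65 (SE) in place of 1.08 ± 0.39 (SE). Over all samples Il10-/- Tnfr1-/- replicate 4, at -0.755, lay within the Il10-/- range. The camera call held in every alternative run at the preset correlation. T cell genes were higher in all 8 tested members (camera adjusted p = 0.032, adjusted p = 0.65 with an estimated correlation). Tcrg-C1 was at 1.495 ± 0.664 and 2.98 ± 1.36 and Trac at 1.12 ± 1.09 and 3.22 ± 3.90. Adjusted over the list alone, 0 members were called, and the score differed by 0.60 (exact permutation p = 0.18, adjusted 0.382). The camera call was lost without Il10-/- replicate 1 or 2 (list means 0.71 and 0.54), without Il10-/- Tnfr1-/- replicate 2 or 6 (0.32 and 0.57) and with quantile normalization (0.41). The log2 fold change of Trac went from 0.93 to 0.51 without Il10-/- Tnfr1-/- replicate 2. Of 21 B cell genes, 2 could be tested (camera adjusted p = 0.614; score difference 0.56, exact permutation p = 0.413): Ighm at 4.84 ± 4.37 and 20 ± 29.1, and Cd72 at 6.50 ± 4.26 and 6.49 ± 3.18. That of Ighm was 1.04, and 0.42 and 0.64 without Il10-/- Tnfr1-/- replicate 2 and 3. Without the filter on low values the B cell list passed camera as higher (mean 0.66, adjusted p = 0.0139).

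**Figure D2:**
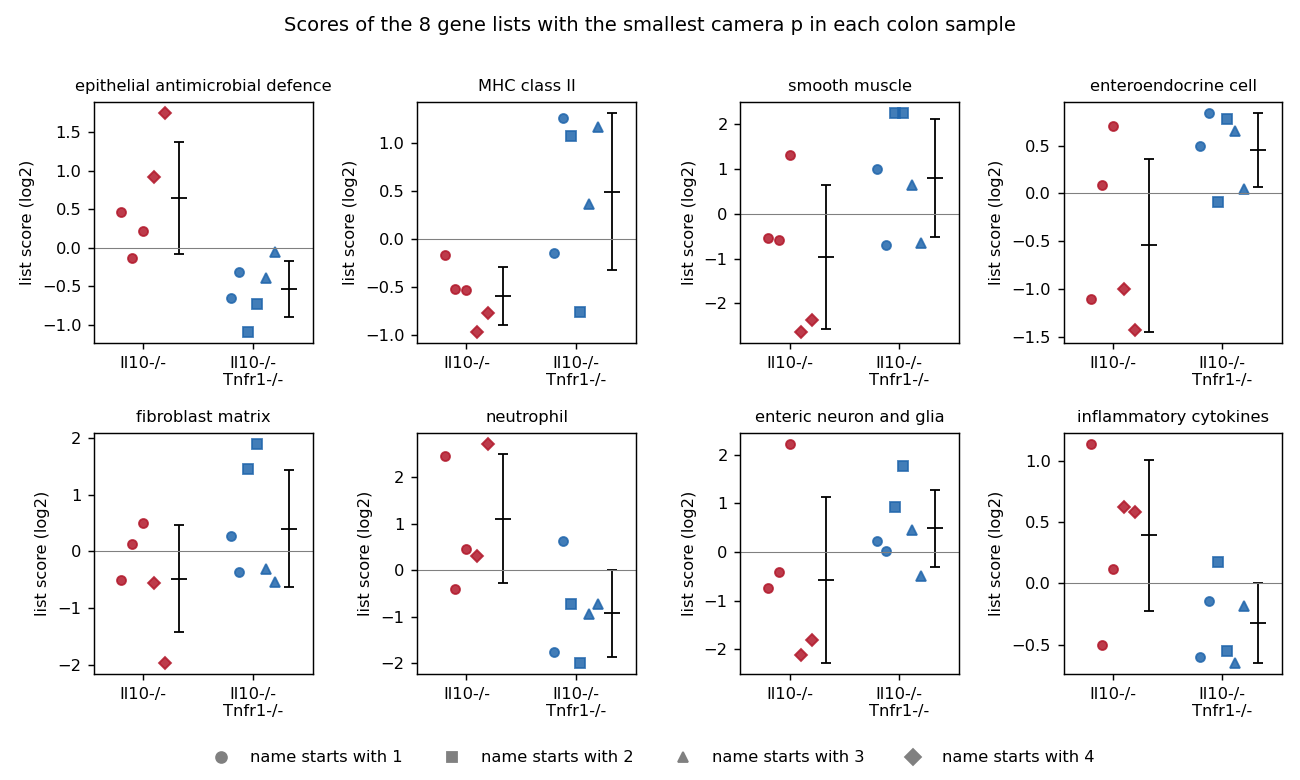
Scores of 8 gene lists in each colon sample, where a score is the mean centred log2 value of the list's tested members; Il10-/- is red (n = 5), Il10-/- Tnfr1-/- is blue (n = 6), marker shape gives the first digit of the sample's name, and bars show the mean and SD. The antimicrobial scores differ by -1.18 between the genotype means, while the smooth muscle scores, which differ by 1.77, spread widely and are lowest in the red samples whose names start with 4.

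Enteroendocrine genes, the hormone and granule genes of the epithelium, were higher in 10 of 12 tested members (camera adjusted p = 0.00119, adjusted p = 0.547 with an estimated correlation). Chgb was at 21.2 ± 11.6 in Il10-/- and 46.6 ± 11.5 in Il10-/- Tnfr1-/- samples (log2 fold change 1.26 ± 0.35, SE). Gcg, the proglucagon gene, was at 33.7 ± 17.3 and 59.1 ± 7.81. Tph1, whose product starts serotonin synthesis, was at 3.64 ± 2.41 and 7.02 ± 1.62, and Chga at 26.5 ± 14.2 and 44.6 ± 13.03. Adjusted over the list alone, 3 were called, all higher. The score differed by 1.00 (exact permutation p = 0.0563, adjusted 0.314), and by 0.77 among names that start with 1 (exact p = 0.4). With the smooth muscle score as a covariate the difference was 0.58 ± 0.44 (SE) in place of 1.00 ± 0.41 (SE), and camera still called the list (adjusted p = 0.0107). Without Il10-/- replicate 1 the camera call was lost (adjusted p = 0.0728), while the list mean was 0.86 and Chgb, Gcg and Tph1 had log2 fold changes of 1.33, 0.94 and 0.81. Mitochondrial fatty acid oxidation genes were higher in 15 of 21 members (camera adjusted p = 0.032, adjusted p = 0.65 with an estimated correlation). Acadm, the medium-chain acyl-CoA dehydrogenase, was at 60.9 ± 11.1 and 91.0 ± 12.3 with no overlap (log2 fold change 0.59 ± 0.16, SE), and Etfdh at 35.6 ± 11.9 and 49.0 ± 8.73. The list had 0 members called when adjusted over the list alone, and its score differed by 0.31 (exact permutation p = 0.169, adjusted 0.382). Among names that start with 1 the score differed by 0.67, more than over all samples (exact p = 0.2, camera adjusted p = 3.59e-10). With the smooth muscle score as a covariate it was 0.55 (camera adjusted p = 1.36e-08). The call over all samples was lost without Il10-/- replicate 1 or 3 (list means 0.14 and 0.31), without Il10-/- Tnfr1-/- replicate 1, 2 or 6 (0.27, 0.25 and 0.24), and with median-ratio size factors (0.24).

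Genes of the muscle wall and stroma were higher in Il10-/- Tnfr1-/- colons, with a very large spread between animals. All 10 tested smooth muscle genes had a higher mean (camera adjusted p = 4.43e-05, adjusted p = 0.65 with an estimated correlation). The enteric actin Actg2 was at 277.2 ± 391 in Il10-/- and 1118 ± 982 in Il10-/- Tnfr1-/- samples (log2 fold change 2.57 ± 0.92, SE). The contractile genes Mylk, Lmod1 and Myh11 had log2 fold changes of 1.66, 1.48 and 1.83. The smooth muscle score differed by 1.77 (exact permutation p = 0.0801, adjusted 0.382), but by 0.10 among names that start with 1 (exact p = 1), where the camera call was also lost. The fibroblast matrix list was higher in all 14 members (camera adjusted p = 0.00216, adjusted p = 0.65 with an estimated correlation), with Dcn at 13.2 ± 10.6 and 53.4 ± 61.9, Pdgfra at 4.59 ± 1.83 and 8.41 ± 4.01, Lum at 5.96 ± 4.42 and 20.2 ± 22.5 and Thy1 at 18.0 ± 25.2 and 22.2 ± 9.74. Its score difference among names that start with 1 was -0.09. Enteric neuron and glia genes were higher in 12 of 13 members (camera adjusted p = 0.00897, adjusted p = 0.65 with an estimated correlation), among them the glial gene Gfap (log2 fold change 0.97), while Ret, the receptor of the neuron lineage, was lower (-1.36). The difference of that score was 1.06 over all samples and -0.22 among names that start with 1. Among those names the smooth muscle and neuron differences lean on Il10-/- replicate 3, with scores of 1.306 and 2.21. Il10-/- replicates 1 and 2 had -0.532 and -0.58 for smooth muscle, and -0.75 and -0.42 for neuron. Il10-/- Tnfr1-/- replicates 1 and 2 had 1.007 and -0.688 for smooth muscle, and 0.234 and 0.01 for neuron. The scores of the matrix and neuron lists had exact permutation p-values of 0.197 and 0.201 (adjusted 0.382 for each), and 0 members of the smooth muscle, matrix and neuron lists were called when each was adjusted over the list alone. The calls of the matrix and neuron lists were lost among names that start with 1 and without Il10-/- replicate 1 (list means 0.88 and 1.02), and that of the neuron list also without Il10-/- replicate 5 (0.67). With the smooth muscle score as a covariate both were lost, at -0.14 ± 0.41 (SE) in place of 0.88 ± 0.60 (SE) for matrix and -0.36 ± 0.41 (SE) in place of 1.06 ± 0.78 (SE) for neuron. Single animals moved these means: the matrix mean was 0.51 without Il10-/- replicate 6 and 0.59 without Il10-/- Tnfr1-/- replicate 4, and the neuron mean was 1.76 without Il10-/- replicate 3. The log2 fold changes of Dcn and Lum were 1.17 and 0.82 without Il10-/- replicate 6 in place of 1.83 and 1.38, and that of Thy1 was 1.57 without Il10-/- replicate 3 in place of 0.94.

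Endothelial and erythroid genes were higher over all samples as well. Vwf (log2 fold change 0.82) and Cdh5 (0.95) were the members of smallest p of the endothelium list (10 of 12 members higher, camera adjusted p = 0.0302, adjusted p = 0.65 with an estimated correlation). The near-identical globin genes Hbb-bt (1.17) and Hbb-bs (0.93) were those of the erythroid list (4 of 4, camera adjusted p = 0.0269, adjusted p = 0.65 with an estimated correlation). For both lists 0 members were called when adjusted over the list alone, and the scores had exact permutation p-values of 0.219 and 0.0931 (adjusted 0.382 for each). Both turned negative among names that start with 1, with score differences of -0.39 and -0.22, and there the endothelium list passed camera in the opposite direction (adjusted p = 0.0105). Over all samples the endothelium call, at a list mean of 0.52, was lost without Il10-/- replicate 1 or 5 (0.46 and 0.45) and without Il10-/- Tnfr1-/- replicate 3, 4 or 6 (0.33, 0.34 and 0.52). With an equal total per sample it was lost at a larger mean, 0.64 (adjusted p = 0.0624). Cdh5 went to 0.62 without Il10-/- replicate 6. The erythroid call, at a mean of 0.96, was lost without Il10-/- replicate 1 or 5 (0.99 and 0.72) and without Il10-/- Tnfr1-/- replicate 5 or 6 (0.83 and 0.71), and its mean was 0.61 without the filter on low values. With the smooth muscle score as a covariate both were lost, at -0.10 ± 0.31 (SE) in place of 0.52 ± 0.39 (SE) and 0.66 ± 0.63 (SE) in place of 0.96 ± 0.51 (SE). In all, 13 of the 39 lists passed camera with the preset correlation, 0 did with an estimated correlation or with fry, and 0 list scores passed the exact test after adjustment. Without Il10-/- replicate 1, 3 lists passed: antimicrobial defence, MHC class II and smooth muscle. The other 10 kept the direction of their mean, at 45.4% of the value over all samples for fatty acid oxidation and between 74.2% and 117.5% for the rest.

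Genes known to respond to TNF showed no detectable difference as a group. Of 22 tested genes of the TNF and NF-kB response list, 10 were higher and 12 lower (camera adjusted p = 0.786; score difference -0.01, exact permutation p = 0.959). Ptgs2, the inducible cyclooxygenase, had a log2 fold change of 0.91 ± 0.34 (SE), but 0.09 among names that start with 1 (exact p = 1), and the adhesion gene Vcam1 had 0.84 ± 0.39 (SE). The TNF superfamily of receptors and ligands divided evenly, 9 higher and 9 lower (camera adjusted p = 0.554), with Tnfrsf11b at 1.14 ± 0.39 (SE) and Tnf as above. Its median and mean log2 fold changes were 0.03 while camera's direction was down. Interferon gamma response genes (13 of 21 lower, camera adjusted p = 0.221) included Nos2, the inducible nitric oxide synthase, at 22.8 ± 16.4 and 4.79 ± 1.66, and Irf1 (log2 fold change -0.48, and -0.28 without Il10-/- replicate 6). That list passed camera as lower without Il10-/- replicate 2 or 3 and without Il10-/- Tnfr1-/- replicate 5 or 6 (adjusted p between 0.0356 and 0.0458). Macrophage and monocyte genes (13 of 16 higher, camera adjusted p = 0.141) included Apoe (0.92) and, in the other direction, Cd14 (-0.92, and -0.60 without Il10-/- replicate 1), and passed as higher without the filter (adjusted p = 0.0453) and without Il10-/- Tnfr1-/- replicate 1 (adjusted p = 0.0464). Mature colonocyte genes were mixed (11 higher and 12 lower, camera adjusted p = 0.554, with a median log2 fold change of -0.10 and a mean score difference of 0.19). They passed camera as higher with the first digit of the name (mean 0.66, adjusted p = 0.0463) or the smooth muscle score (mean 0.74, adjusted p = 0.0169) as a covariate, but the same mean of 0.66 among names that start with 1 did not pass (adjusted p = 0.0678). Among them Car4, an apical carbonic anhydrase, was at 488.6 ± 510 and 74.2 ± 39.3, and the sodium channel subunit Scnn1b had a log2 fold change of -0.72. Goblet cell genes were mixed too (5 higher and 13 lower, camera adjusted p = 0.331), with Atoh1 (0.72) and Ccl9 (0.89) higher on average.

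The spread of list scores between animals did not differ detectably between the genotypes: of the 39 list scores, 0 had a variance ratio that passed the exact permutation test after adjustment (smallest adjusted p = 0.778). For MHC class II the variance in Il10-/- Tnfr1-/- samples was 7.49 times that in Il10-/- samples (exact permutation p = 0.0238). The second principal component of the genes, with 21.8% of the variance, had an SD of 48.3 in Il10-/- and 14.7 in Il10-/- Tnfr1-/- samples. On it Il10-/- replicates 1 and 3 lay far apart, at 77.5 and -57.4, and this difference in spread was not tested. The first principal component of the genes held 37% of the variance, with an SD of 40.9 in Il10-/- and 36.9 in Il10-/- Tnfr1-/- samples, and did not separate the genotypes (exact permutation p = 0.126, adjusted 0.188 over 3 components). This component correlated with the smooth muscle score over the 11 samples (r = -0.85, permutation p = 0.00101, adjusted 0.00168 over 5 relations; rho = -0.745, permutation p = 0.0113; r = -0.71 without 2 samples).

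DNA flanking a deleted gene can derive from another mouse strain, so the genes near Tnfrsf1a were compared with the rest. Of 134 tested genes within 10 Mb, 0 passed limma's adjusted threshold, as elsewhere, which leaves the planned Fisher's exact test without a difference to find (p = 1). At an unadjusted p under 0.05, a threshold chosen after seeing the data, there were 15 of 134 (11.2%) against 1089 of 12978 (8.39%) elsewhere, an odds ratio of 1.38 with a Fisher's exact p of 0.271.

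Within names that start with 1, 3 Il10-/- against 2 Il10-/- Tnfr1-/- samples, limma called 0 of 13293 genes, with 139 at an unadjusted p under 0.05 and a smallest adjusted p of 1. Of 59 named genes, 24 had a log2 fold change there that differed by more than 1.5 times from the one over all samples: 22 were smaller, 5 of them with the other sign, and 2 were larger. The smaller ones included Saa2 (-1.56), S100a8 (-2.43), Ltf (-0.11), Car4 (-1.33), Actg2 (0.64), Mylk (0.21), Lmod1 (0.04), Myh11 (0.09), Dcn (0.30), Lum (0.24), Thy1 (0.49), Gfap (0.06), Apoe (0.27) and Tnfrsf11b (0.57), beside Saa1, Il18 and Ptgs2 as above; Ccl9 (1.36) and Cd72 (0.36) were larger. The log2 fold changes there correlated with those over all samples at r = 0.52 across genes, which are not independent replicates, and these 5 samples are also part of the larger comparison. No difference between genotypes was detected in signs of library make-up: retained-intron transcripts carried 7.79% ± 1.99 (SD, n = 5) of the value in Il10-/- and 6.29% ± 0.902 (SD, n = 6) in Il10-/- Tnfr1-/- samples (exact permutation p = 0.147, adjusted 0.36 over 4 measures), and mitochondrial genes 16.6% ± 5.29 and 18.0% ± 5.01 (exact permutation p = 0.654, adjusted 0.654). Transcripts at 0 made up 49.5% ± 4.47 and 46.1% ± 3.40 (exact permutation p = 0.18, adjusted 0.36), and the summed value had an exact permutation p of 0.297 (adjusted 0.396). Several of these signs followed the first principal component of the transcripts, which held 49.9% of their variance. Over the 11 samples, with the sign of the component set by the retained-intron share, that share gave r = 0.922 (permutation p = 4e-05, adjusted 2e-04; rho = 0.873, permutation p = 0.00098; 0.87 without 2 samples). The share of transcripts at 0 gave r = 0.913 (permutation p = 0.00014, adjusted 0.00035; rho = 0.8, permutation p = 0.00473; 0.861 without 2 samples). The summed value gave r = 0.731 (permutation p = 0.00723, adjusted 0.00904; rho = 0.7, permutation p = 0.0209), which fell to 0.373 without 2 samples and so rests on them, and the mitochondrial share gave r = -0.428 (permutation p = 0.186, adjusted 0.186; rho = -0.427, permutation p = 0.191; -0.271 without 2 samples). Names that start with 1 are 5 samples, fewer than the 6 required here for a correlation, so these relations were not computed within them.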

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

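All tests of explanations for the antimicrobial, muscle wall and Ly6g patterns were chosen after the result was seen; the tests of other splits were written before any split was run, when the real counts were already known.

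The search for samples far from the rest of their genotype covered 158 groups of values for the named genes and list scores and found 9, where chance gives about 1 in 20, or 7.9. Il10-/- replicate 3 was far above the other 4 for Thy1 (63.1 against 5.36 to 8.85), Apoe (219.5 against 49.3 to 66.2) and Vwf (9.155 against 3.165 to 4.293). Il10-/- replicate 1 was far above the others for Trac (3.058 against 0.483 to 0.787). Il10-/- Tnfr1-/- replicate 3 was far below the others for Ltf (0.8289 against 2.477 to 2.793) and far above them for Scnn1b (9.542 against 3.395 to 4.168). Il10-/- Tnfr1-/- replicate 1 was far below the others for Nos2 (1.835 against 4.301 to 6.589), replicate 5 for Etfdh (32.12 against 47.5 to 55.4) and replicate 6 for the squamous epithelium score (-0.68 against -0.29 to -0.06).

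The antimicrobial defence list was lower in Il10-/- Tnfr1-/- colons. A smaller share of epithelium would lower the colonocyte and goblet cell scores alike, but the antimicrobial score minus the mean of those scores still differed by -1.199 (exact permutation p = 0.00216, the smallest possible), which argues against that explanation. A larger share of muscle wall stays open for part of the difference in the antimicrobial score itself. With the smooth muscle score as a covariate that score differed by -0.661 ± 0.278 (SE) in place of -1.179 ± 0.337 (SE), still past camera (adjusted p = 0.0164). Relative to the colonocyte and goblet cell scores it moved less, from -1.199 ± 0.263 (SE) to -1.065 ± 0.325 (SE). A muscle share that lowers these epithelial scores alike cancels in that contrast. The covariate could therefore hardly move the contrast, and this step decides nothing about muscle share. Among names that start with 1 the difference was -0.659 (exact permutation p = 0.2, where 0.1 is the smallest possible), so the genotype and the unexplained groups of names cannot be told apart for this list with 3 animals against 2. The loss of TNF receptor 1 stays open as a biological explanation.

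Smooth muscle, enteric neuron and matrix genes were higher in Il10-/- Tnfr1-/- colons. A varying share of muscle wall in the sampled tissue is a candidate explanation: over the 11 animals the group-centred smooth muscle and neuron scores correlated at r = 0.91 (permutation p = 1e-05, the smallest 100000 permutations can give; rho = 0.909, permutation p = 0.00035; adjusted p = 2e-05 over 2 relations), and at 0.89 without the 2 samples farthest from the median. A difference in RNA make-up stays open. The smooth muscle score and the retained-intron share gave r = -0.035 (permutation p = 0.92, rho = -0.109 with permutation p = 0.756, and r = -0.34 without 2 samples). With that share as a covariate the lists still passed camera (adjusted p = 1.72e-05, 6.69e-05 and 0.0147). The score differences, with the SE between animals, went from 1.77 ± 0.88 to 1.72 ± 1.06 for smooth muscle. They went from 1.06 ± 0.78 to 1.36 ± 0.92 for neuron and from 0.88 ± 0.60 to 0.57 ± 0.69 for matrix. None was then beyond 2 SE, but neuron and matrix were within 2 SE without the covariate too. The smooth muscle estimate hardly moved, so the wider SE does not speak for this explanation. Among names that start with 1 the smooth muscle score differed by 0.095 (exact permutation p = 1), so the genotype and the groups of names cannot be told apart for it. The small difference within those names leans on Il10-/- replicate 3, at 1.306 against -0.532 and -0.58 in Il10-/- replicates 1 and 2. A biological difference by genotype stays open and untested.

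Ly6g lay above S100a8 in 9 of 11 animals, from nearly equal (171.5 against 170.2) to 46.6 against 0.116, and below it in the other 2. Neutrophils stay open as a source: Ly6g correlated with the neutrophil receptor genes Csf3r (r = 0.793, permutation p = 0.00575, adjusted p = 0.0103, with rho = 0.764, permutation p = 0.00859, and r = 0.774 without 2 samples) and Cxcr2 (r = 0.822, permutation p = 0.00237, adjusted p = 0.00711, with rho = 0.891, permutation p = 6e-04, and r = 0.727 without 2 samples). Both genes were too low to pass the filter for the gene test. Csf3r lay between 0.036 and 2.49 and Cxcr2 between 0.253 and 0.979, so these relations rest on values near the floor. Reads of other Ly6 genes counted as Ly6g would need shared sequence, and 9.55% of the 31-base words of the Ly6g transcript that carries the values occurred in other genes, narrowly under a bound of 10% that was set after shared counts for single genes had been seen; strain variants were not tested. Ly6g also correlated with its neighbour Ly6a, at r = 0.916 (permutation p = 0.00015; rho = 0.909, permutation p = 0.00028; 0.895 without 2 samples; adjusted p = 9e-04 over 6 relations), and with Ly6d (r = 0.762, permutation p = 0.00689, adjusted 0.0103; rho = 0.682, permutation p = 0.0256; 0.595 without 2 samples), but a relation was detected neither with Gml of the same cluster (r = 0.261, permutation p = 0.432, adjusted 0.432; rho = 0.273, permutation p = 0.418; -0.071 without 2 samples) nor with S100a8 (r = 0.425, permutation p = 0.194, adjusted 0.233; rho = 0.327, permutation p = 0.328; 0.13 without 2 samples). A source shared with Ly6a is a candidate explanation found and tested on the same data.

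Chance could not be excluded for the counts by genotype. Of 100 splits of the 11 samples into 5 and 6, the real one included, 17 gave at least the 1117 genes at an unadjusted p under 0.05 of the real split, with 3888 as the highest of the other splits. As many as the real 13 gene lists passed camera in 22 splits, with a median of 9 lists in the other splits and 21 as the highest. As many as the real 78 genes without overlap came from 21 splits, with 836 as the highest other. For genes and transcripts past the adjusted threshold the real count was 0 and all 100 splits match or exceed it by construction, with 2 genes and 3995 transcripts as the highest of the others. The split with 3888 genes and 3995 transcripts set Il10-/- replicates 3, 5 and 6 and Il10-/- Tnfr1-/- replicates 5 and 6 apart, which are all names that start with 3 or 4 plus 1 that starts with 1. With these 2 sets of samples as a covariate, told apart by whether Ptges3-ps was above 0 and chosen after seeing the data, limma called 0 genes by genotype, with 830 at an unadjusted p under 0.05, and camera called 15 lists, the 13 among them. Of the 150 assignments that keep the number of each genotype per set, the real one included, 46 gave at least 830 genes and 22 at least 15 lists, so chance stays open there too.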

How the results depend on the processing

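The scalings, the covariates other than the first digit of the name, limma without robust moderation and the unadjusted threshold near Tnfrsf1a were chosen after seeing the data; the other settings were planned. Over 57 named genes, Tnfrsf1a and Il10 apart, 1346 of 1363 settings kept the direction and the side of the threshold. In 1 setting a gene was called in addition (Il18 without Il10-/- replicate 2), and 16 changed sign. None of these genes was called over all samples, so keeping the side of the threshold meant staying uncalled. The count therefore shows kept signs, not kept sizes: Lmod1 counted as kept throughout, at log2 fold changes between 0.044 and 1.882. Over 20 lists, 371 of 459 settings kept both, 39 lost their call, 9 gained one and 40 changed sign. By limma's adjusted p Tnfrsf1a was called without Il10-/- replicate 2 (0.0333) and with quantile normalization (0.0338), over a range of 0.0333 to 1, and Il10 in none of the settings. The smooth muscle score as a covariate was not applied to the smooth muscle list or its genes, where it would be circular. The settings that need counts (other count tests, count normalizations and length-scaled counts) were not run, and a filter of a value over 1 in 6 samples equals the one used. The unknown depth leaves the precision of low values open.

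Leaving out 1 sample at a time gave 0 to 2 genes, 0 to 1 transcripts and 3 to 16 lists, and ranges of -0.188 to 0.33 for Cd72, -0.106 to 0.1 for the TNF and NF-kB response list, -0.026 to 0.091 for the TNF superfamily list, -0.344 to 0.216 for the interferon gamma list and -0.105 to 0.355 for the mature colonocyte list. Among names that start with 1 and, with the same estimate, with the first digit as a covariate, the log2 fold changes were -0.097 for Pdgfra, -0.215 for Vwf, -0.242 for Cdh5, -0.197 for Hbb-bt and -0.238 for Hbb-bs. The list means there were -0.089 for fibroblast matrix, -0.225 for neuron and glia, -0.039 for macrophage, 0.176 for goblet cell, -0.391 for endothelium, -0.223 for erythroid and 0.062 for TNF and NF-kB response. Among those names Tnfrsf1a (-1.829) and Il10 (-1.368) could not pass an exact test, with fewer samples as the reason. The TNF and NF-kB mean was 0.002 without the filter, 0.007 with a pseudocount of 0.1, 0.121 with an equal total per sample and 0.059 with the smooth muscle score as a covariate. That covariate also gave -0.058 for Cdh5, -0.143 for fibroblast matrix, -0.363 for neuron and glia, 0.207 for interferon gamma, 0.072 for goblet cell and -0.1 for endothelium. Quantile normalization gave 1 gene, 2 list scores, -0.065 for Cd72, 0.007 for goblet cell and -0.122 for the TNF superfamily, which was at -0.03 with median-ratio size factors. An unadjusted threshold near Tnfrsf1a gave 15 genes in place of 0, and an estimated correlation and fry each gave 0 lists. Except where fewer samples or another threshold is the reason, the cause was not tested.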

Other observations

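The genes given here were singled out after their values were seen, and no test of them was planned.

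Antimicrobial lectin genes varied widely between animals of either genotype. Reg3b ranged from 9.32 in Il10-/- replicate 1 to 25420 in Il10-/- replicate 6, and from 50.1 to 4966 over the 6 Il10-/- Tnfr1-/- samples. Its neighbour Reg3g was at 7.43 and 6898 in the same Il10-/- samples. Il10-/- replicate 1, with the lowest Reg3b, had the highest abundance of Cxcl9, an interferon gamma-induced chemokine (7.16, against 0.176 to 1.93 in the other 10 samples), of Ly6a (1865) and of Tnfrsf1b, the other TNF receptor (20.6). The Ly6 cluster gene Ly6d was at 50.6 ± 43.6 (SD, n = 5) in Il10-/- and 10.1 ± 18.1 (SD, n = 6) in Il10-/- Tnfr1-/- samples.

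The pseudogene Ptges3-ps was at 0 in 5 samples, Il10-/- replicates 3, 5 and 6 and Il10-/- Tnfr1-/- replicates 5 and 6, and between 32.3 and 82.9 in the other 6. The mitochondrial gene mt-Nd4l ranged from 810.7 to 6809, and Dhtkd1 from 2.60 to 4.89 in those 6 samples and from 9.03 to 18.1 in the 5. The Y-linked gene Eif2s3y was below 1 in 3 libraries, 2 Il10-/- (replicates 3 and 6) and 1 Il10-/- Tnfr1-/- (replicate 1). Both genotypes therefore include animals with and without Y-linked signal, while the labels do not give sex. Y-linked signal was not used as a covariate, so its part in any difference was not tested.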
